A study of Mus musculus with 16 samples.

How the data were processed

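Gene expression was measured by sequencing of polyA-selected RNA from the lumbar dorsal root ganglia (DRG) of C57BL/6 mice with carrageenan-induced paw inflammation. The 16 libraries fall into 3 groups by intrathecal treatment, taken from the sample labels: vehicle (PBS, n = 5), the IL4-10 fusion protein (n = 6) and the unlinked cytokines IL4 and IL10 together, called the combination here (n = 5). The labels do not say that each sample came from a different mouse, so the p-values measure spread between these samples.

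Per the submitters' processing notes, reads were checked with FastQC, aligned with STAR to build GRCm38, counted with HTSeq and handled with DESeq2; no versions are given. The deposited table holds 36722 genes. The values deposited by the authors are variance-stabilised values on a log2 scale. A transform with 2 parameters, fitted to the 60 lowest of 11441 distinct values, maps 100% of the values to whole numbers within 0.01. The libraries had therefore been scaled and rounded before the transform by a step that is not stated, and the read depth of each library is unknown. The whole numbers are called scaled values here; they are not read counts, and no counting interval is given. The lowest value, 5.99, decodes to 0 and occurs 34 times in 2 libraries, fusion protein replicates 5 (7 times) and 6 (27 times). Genes not detected sit at 6.17, which decodes to 1. Near this floor the transform compresses differences, so a log2 difference of a weakly expressed gene is smaller than the log2 of the ratio of its scaled values. The GC content column of the authors is in percent per the file headers. The table also holds a deposited p-value and a deposited adjusted p-value per gene, in columns whose headers do not name the comparison; they were not used for calls.

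Genes were tested when their mean over all 16 libraries was at least 1 above the lowest value of the table, a log2 value of 6.99 or a scaled value of 31.8. This left 13385 genes. The 3 comparisons were tested in 1 model of all libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All differences are log2 differences between group means with the SE of limma. Coordinates and exonic lengths came from the GENCODE annotation of GRCm38: 36429 genes matched by identifier, and a length was found for 99.9% of the tested genes. Python 3.11.15 was used for the annotation and the plots.

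Before the data were examined, 43 gene lists were fixed for pathways, channels, receptors and the cell types that dissected DRG can hold; 42 had at least 3 tested members and were tested. Lists were tested with camera of limma at a preset correlation of 0.01 (adjusted over the 42 lists of a comparison), beside camera with an estimated correlation and fry. Members are counted after adjustment over all tested genes and, in the words used here, adjusted over the list alone. The correlation of the differences of both treatments was set beside 100 simulations without effect, with errors independent between genes. It was also set beside 20 splits of the vehicle libraries into separate groups, since both comparisons share the vehicle libraries.

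Genes named in the text follow a rule fixed before the data were examined: in each comparison the 10 largest increases and 10 largest decreases among genes past the threshold with an established symbol (548 tested genes carry a predicted-gene symbol), up to 4 members with the lowest p of each list past its threshold, and a panel of 10 receptor and signalling genes of IL4 and IL10. Socs1 of this panel lay below the filter. Of the genes so named, those that matter are given with their values and the rest as counts. Any other gene is said to have been chosen after its values were seen.

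The slope of each library on gene properties was measured as the change in its deviation from the mean of all libraries per SD of GC content or of log2 exonic length. These slopes were compared between groups with exact permutation tests, two-sided. The labels also number the samples, from 1 to 8 and from 12 to 19. All combination libraries, 2 of the fusion protein libraries and 1 vehicle library have the later numbers, so this split was tried as a covariate. It overlaps strongly with the combination group, which lowers the precision of comparisons with that group. A call that ended with it can therefore reflect lost precision where the difference stayed about as large.

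Alternatives fixed before the data were examined were a stricter filter and none, quantile normalization, median centring, limma without trend and robust, array weights, fits of only the groups compared, a block for the replicate number, the late label number, the first residual principal component, log2 of the decoded value plus 1, adjusted p thresholds of 0.1 and 0.01, and the omission of each library. Chosen after seeing the data were the removal of trends with GC content and length (natural splines with 5 degrees of freedom each, fitted per library), this removal together with the late label number, and the omission of fusion protein replicate 1 with vehicle replicate 1. The effect of alternatives on single lists was examined for 10 lists, and for all 42 without fusion protein replicate 1, an extension also chosen after seeing the data.

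The model was tested on simulated data with the means and spreads of the 13385 genes and 200 genes changed in each treated group, in 5 runs. A change of 0.5 was found in 89.6% of 500 genes for the fusion protein against vehicle, 87.8% for the combination against vehicle and 91.4% of 994 for the direct comparison. Among unchanged genes 0.0683%, 0.0698% and 0.115% were called. A list shifted by 0.5 in the fusion protein group alone passed in 5 of 5 runs in both comparisons with that group and in 0 of 5 for the combination against vehicle, where it was not shifted. No other list passed. The simulated errors were independent between genes, so these runs cannot show how correlation between genes affects the calls of genes or lists in the real data.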

Results

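RNA of lumbar DRG, the ganglia that hold the cell bodies of sensory neurons with their glia and resident immune cells, was measured in mice 6 days after an injection of 20 µl of 2% carrageenan into the paw. At that time the mice received an intrathecal injection of PBS (vehicle, n = 5), 1 µg of the IL4-10 fusion protein (n = 6) or 0.5 µg each of IL4 and IL10 (combination, n = 5), and the ganglia were taken 6 hours later. The fusion protein joins both anti-inflammatory cytokines in a single molecule, and the title of the series sets its transcriptome against that of the combination. The read depth is unknown. The scaled values, which are not read counts, summed to 17.8 ± 0.609 M per vehicle library (mean ± SD), 17.8 ± 0.753 M per fusion protein library and 19.6 ± 0.973 M per combination library.

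Libraries of different groups leaned differently on gene length and GC content. The slope on log2 exonic length was 0.0716 ± 0.0299 (SD, n = 5) in vehicle, -0.0493 ± 0.0241 (n = 6) in fusion protein and -0.0124 ± 0.0233 (n = 5) in combination libraries, in log2 units per SD of log2 length. It was lower in both treated groups than in vehicle (exact permutation p = 0.00216 for the fusion protein and 0.00794 for the combination; adjusted over 6 tests, 0.013 and 0.0159). For the fusion protein against the combination the exact permutation p was 0.0433 (adjusted, 0.052). The slope on GC content was 0.0706 ± 0.0602 in vehicle, 0.0153 ± 0.0589 in fusion protein and -0.0888 ± 0.0446 in combination libraries. The combination differed in this slope from vehicle (exact permutation p = 0.00794, adjusted 0.0159) and from the fusion protein (0.0173, adjusted 0.026), while the fusion protein against vehicle gave 0.154.

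**Figure D1:**
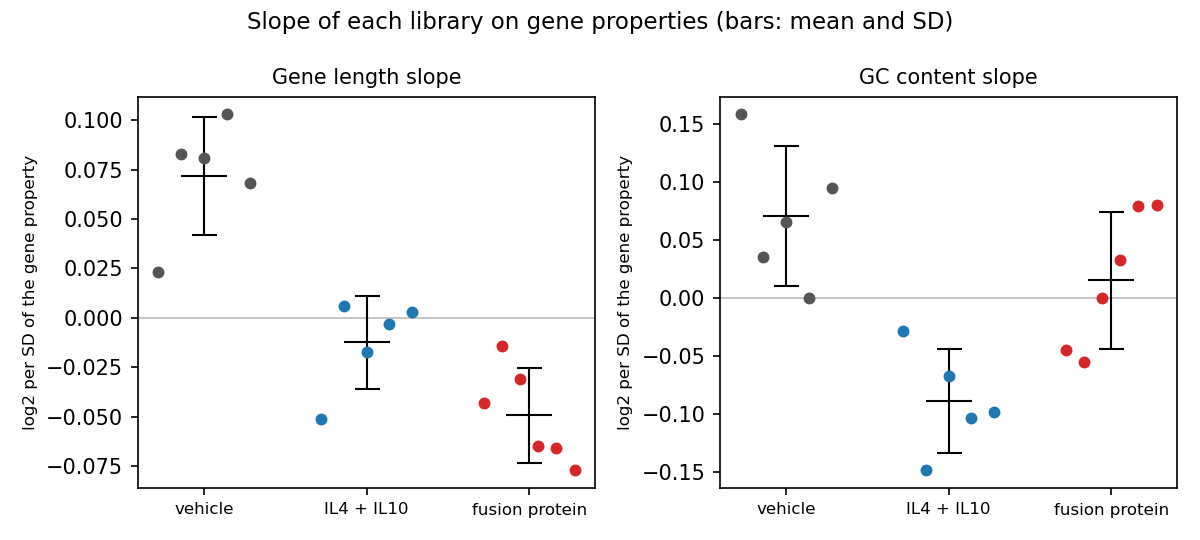
Slope of each library on log2 exonic length (left) and GC content (right), in log2 units per SD of the gene property, by treatment group; points are libraries and bars are the mean and SD. All 5 vehicle libraries, at 0.023 or above, lie above the 11 treated libraries, at 0.006 or below, on the length slope.

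The first comparison asks what the fusion protein changed against vehicle. Interferon-response genes had the largest median difference of the 42 lists. Of 30 members 26 rose, 0 fell and 4 did not pass, and 28 rose when adjusted over the list alone. The median log2 difference was 0.96, with a camera adjusted p = 1.9e-22, and adjusted p = 0.134 with an estimated correlation. Isg15, a ubiquitin-like antiviral protein (ENSMUSG00000035692, GRCm38 chromosome 4, 156199424 to 156200818), rose by 2.19 ± 0.10 (SE), from a scaled value of 62.8 ± 17.1 (SD, n = 5) to 633 ± 97.4 (n = 6), with all 6 fusion protein libraries above every vehicle library (adjusted p = 6.46e-11). Irf7, a transcription factor that amplifies interferon signalling (chromosome 7, 141262706 to 141266481), rose by 1.66 ± 0.12, Gbp2, a guanylate-binding protein of cell-autonomous defence, by 1.98 ± 0.42, and Oas1a, a sensor of double-stranded RNA, by 0.89 ± 0.09. Per library the list median was 0.95 ± 0.28 (SD, n = 6) above the vehicle mean, from 0.54 to 1.36, while vehicle libraries reached 0.19 at most. On the scale of log2 of the decoded value plus 1, which does not compress low values, the list median was 1.47.

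Of 17 tested pro-inflammatory and NF-kB genes, 10 rose, 0 fell and 7 did not pass, and 12 rose when adjusted over the list alone. The median was 0.69, with a camera adjusted p = 1.68e-08, and adjusted p = 0.295 with an estimated correlation. Among them the chemokine Ccl5 rose by 2.00 ± 0.16 (adjusted p = 6.41e-07), from a scaled value of 18.4 to 327, Cxcl10, a chemokine for activated T cells, by 1.29 ± 0.21, the receptor Tlr2 by 0.91 ± 0.13 and the adhesion molecule Vcam1 by 0.70 ± 0.11. The list median was 0.33 with 3 members called under the stricter filter, and 0.45 without fusion protein replicate 1 and vehicle replicate 1, an omission chosen after seeing the data. Macrophage markers rose in 13 of 21 cases with 0 lower and 8 not passed, and 14 when adjusted over the list alone. The median was 0.44, with a camera adjusted p = 2.45e-07, and adjusted p = 0.295 with an estimated correlation. Ctss, a lysosomal protease of antigen-presenting cells, rose by 1.53 ± 0.17, and the signalling adaptors Fcer1g and Tyrobp by 1.34 ± 0.21 and 1.15 ± 0.21. Complement genes rose in 7 of 14 cases with 0 lower and 7 not passed, and 7 when adjusted over the list alone. The median was 0.31, with a camera adjusted p = 4.7e-05, and adjusted p = 0.211 with an estimated correlation. Among them C3, the central complement component, rose by 1.08 ± 0.18. Neutrophil and bone marrow markers did not pass as a list (3 higher, 1 lower and 9 not passed of 13, 5 and 1 over the list alone, median 0.22, camera adjusted p = 0.0898, and 0.992 with an estimated correlation).

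Of 26 IL-10/STAT3 targets, 11 rose, 0 fell and 15 did not pass, and 13 rose when adjusted over the list alone. The median was 0.40, with a camera adjusted p = 2.61e-05, and adjusted p = 0.639 with an estimated correlation. Slfn4 and Fcgr1, which interferons also induce, rose by 3.02 ± 0.35 and 1.18 ± 0.18. Saa3, an acute-phase protein, rose by 2.62 ± 0.39 and Il1rn, the antagonist of the IL-1 receptor, by 1.77 ± 0.32. Without fusion protein replicate 1 the list median was 0.18 with 8 members called. Without vehicle replicate 4 it was 0.26 with 7 called, and under the stricter filter 7 were called. Per library the list median minus the vehicle mean was 1.161 in fusion protein replicate 1 and 0.11 to 0.43 in the other 5. Vehicle libraries ran from -0.255 to 0.441, so only replicate 1 lay above all of them. Slfn4 (ENSMUSG00000000204, chromosome 11, 83175186 to 83190216) was the largest increase of the comparison, with scaled values of 99.8 ± 38.4 in vehicle and 1895 ± 1696 (SD, n = 6) with the fusion protein. Replicate 1 of that group stood at 5286, and the other 5 at 1217 ± 383.9 (SD). The log2 difference of Slfn4 was 2.68 without it. Of the receptor chains of both cytokines, Il4ra (ENSMUSG00000030748, chromosome 7, 125552120 to 125579474) rose by 0.59 ± 0.16 (adjusted p = 0.0124), Il13ra1 by 0.58 ± 0.16, Il2rg by 0.51 ± 0.11 and Il10ra by 0.51 ± 0.10. The list of receptor chains and signalling parts gave 4 higher, 3 lower and 6 not passed of 13, and 5 and 3 when adjusted over the list alone. It did not pass (median 0.11, camera adjusted p = 0.338, and 0.989 with an estimated correlation). Il10rb did not pass (0.16 ± 0.06), nor did the transcription factors Stat3 (-0.00 ± 0.09) and Stat6 (0.12 ± 0.06) or the feedback inhibitors Socs3 (0.44 ± 0.46) and Cish (-0.08 ± 0.10). Arg1, a marker of alternatively activated macrophages, rose by 1.93 ± 0.25, and Il1b, a pyrogenic cytokine, by 1.80 ± 0.36. Mgl2, a lectin of such macrophages, fell by 0.53 ± 0.13 (adjusted p = 0.0053). Of 18 IL-4/STAT6 targets, 4 rose, 1 fell and 13 did not pass, and 5 and 1 when adjusted over the list alone. The list did not pass (median 0.09, camera adjusted p = 0.245, and adjusted p = 0.992 with an estimated correlation), and over the omissions of a library its median ran from 0.001 without fusion protein replicate 1 (0.546) to 0.169 without vehicle replicate 1 (0.0682). Nor did it pass for the combination against vehicle (3 higher, 2 lower and 13 not passed, 2 and 2 over the list alone, median -0.03, 0.557 and 0.957), where the median ran from -0.033 to 0.005 over the omissions and was 0.15 with the late label number (0.923).

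Ribosomal protein genes rose in 62 of 73 cases with 0 lower and 11 not passed, and 66 when adjusted over the list alone. The median was 0.39, with a camera adjusted p = 4.97e-27, and adjusted p = 0.107 with an estimated correlation. Among them Rps3 rose by 0.51 ± 0.06. Nuclear genes of oxidative phosphorylation rose in 41 of 73 cases with 0 lower and 32 not passed, and 52 when adjusted over the list alone. The median was 0.30, with a camera adjusted p = 2.72e-18, and adjusted p = 0.134 with an estimated correlation. Uqcrb, a subunit of respiratory complex III, rose by 0.66 ± 0.07. The length slope of the libraries differed between the groups. With trends of GC content and length removed, the oxidative phosphorylation median was 0.13 with 21 members called, and Uqcrb differed by 0.36. Unfolded protein response genes rose in 8 of 17 cases with 0 lower and 9 not passed, and 10 when adjusted over the list alone. The median was 0.23, with a camera adjusted p = 0.000144, and adjusted p = 0.295 with an estimated correlation. Pdia6, a disulfide isomerase, rose by 0.43 ± 0.06 and Hspa5, the main chaperone of the endoplasmic reticulum, by 0.49 ± 0.08. Heat-shock genes, which share Hspa5, gave 5 higher, 1 lower and 8 not passed of 14, and 7 higher and 1 lower when adjusted over the list alone. For them camera gave adjusted p = 0.00421, and adjusted p = 0.295 with an estimated correlation. Hspa8 rose by 0.37 ± 0.07 and Bag3, a cochaperone, fell by 0.50. Nerve injury and regeneration genes gave 6 higher, 2 lower and 8 not passed of 16, and 7 and 3 when adjusted over the list alone. The median was 0.24, with a camera adjusted p = 0.0196, and adjusted p = 0.372 with an estimated correlation. Without fusion protein replicate 1 the median was 0.21 with 6 higher and 3 lower, and the list did not pass (adjusted p = 0.0559). Against the name of the list, Lifr, a receptor of leukaemia inhibitory factor, differed by -0.49 ± 0.11.

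Of 32 potassium channel genes, 20 fell, 0 rose and 12 did not pass, and 24 fell when adjusted over the list alone. The median was -0.28, with a camera adjusted p = 2.45e-07, and adjusted p = 0.295 with an estimated correlation. Kcnc4, a channel of fast repolarisation, differed by -0.41 ± 0.07. Without vehicle replicate 4 the list had 12 members called, and with the trends of GC content and length removed together with the late label number its median was -0.18. Of 23 sodium and calcium channel genes 8 fell, 0 rose and 15 did not pass, and 10 fell when adjusted over the list alone. The median was -0.18, with a camera adjusted p = 3.73e-05, and adjusted p = 0.38 with an estimated correlation. Cacna1a, the pore of P/Q-type calcium channels, differed by -0.72 ± 0.06. With the GC and length trends removed the list median was -0.10. Circadian clock genes fell in 5 of 18 cases, with 0 higher and 13 not passed, and 5 when adjusted over the list alone. The median was -0.18, with a camera adjusted p = 0.0196, and adjusted p = 0.295 with an estimated correlation. Nr1d1, a repressor of the clock, differed by -0.47 ± 0.08 and Per1, a core clock component, by -0.49 ± 0.10. Among genes with an established symbol past the threshold, the largest decreases were in Lars2, a mitochondrial leucine tRNA synthetase (-2.59 ± 0.60), the mitochondrial ribosomal RNAs mt-Rnr1 (-1.69 ± 0.49) and mt-Rnr2 (-1.64 ± 0.46), and the nuclear long noncoding RNA Malat1 (-1.39 ± 0.25). The call of mt-Rnr1 ended without vehicle replicate 1 (-1.46, adjusted p = 0.0503) and without vehicle replicate 2 (-1.50, 0.063), and that of mt-Rnr2 without vehicle replicate 2 (-1.46, 0.0535). Lars2 varied widely in vehicle, with a scaled value of 13280 ± 12640 (SD, n = 5). These decreases were not particular to the fusion protein. Without fusion protein replicate 1, Lars2, mt-Rnr1, mt-Rnr2 and Malat1 differed from vehicle by -2.91, -1.94, -1.89 and -1.48. From the combination they differed by only -0.10, -0.40, -0.41 and -0.42. RNA or library quality of the vehicle samples cannot be told apart from the treatments here.

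In all, 1610 genes rose and 1840 fell among the 13385 tested with limma, 80 of them by 1 or more upward and 6 downward. The median exonic length was 2872 bases for the genes that rose and 7159 for those that fell, and the differences correlated with log2 length at r = -0.41 across genes, which are not independent replicates. The 13 lists past the threshold were 10 higher and 3 lower. With an estimated correlation 0 passed and 4 of 42 had an unadjusted p under 0.05, while the same 13 passed with fry. In 64 of 100 splits of the same libraries, the real one included, at least as many lists passed. Among samples numbered 1 to 8 alone (4 against 4), 1026 genes rose and 1137 fell, and the interferon median was 1.03 with 25 members called.

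**Figure D2:**
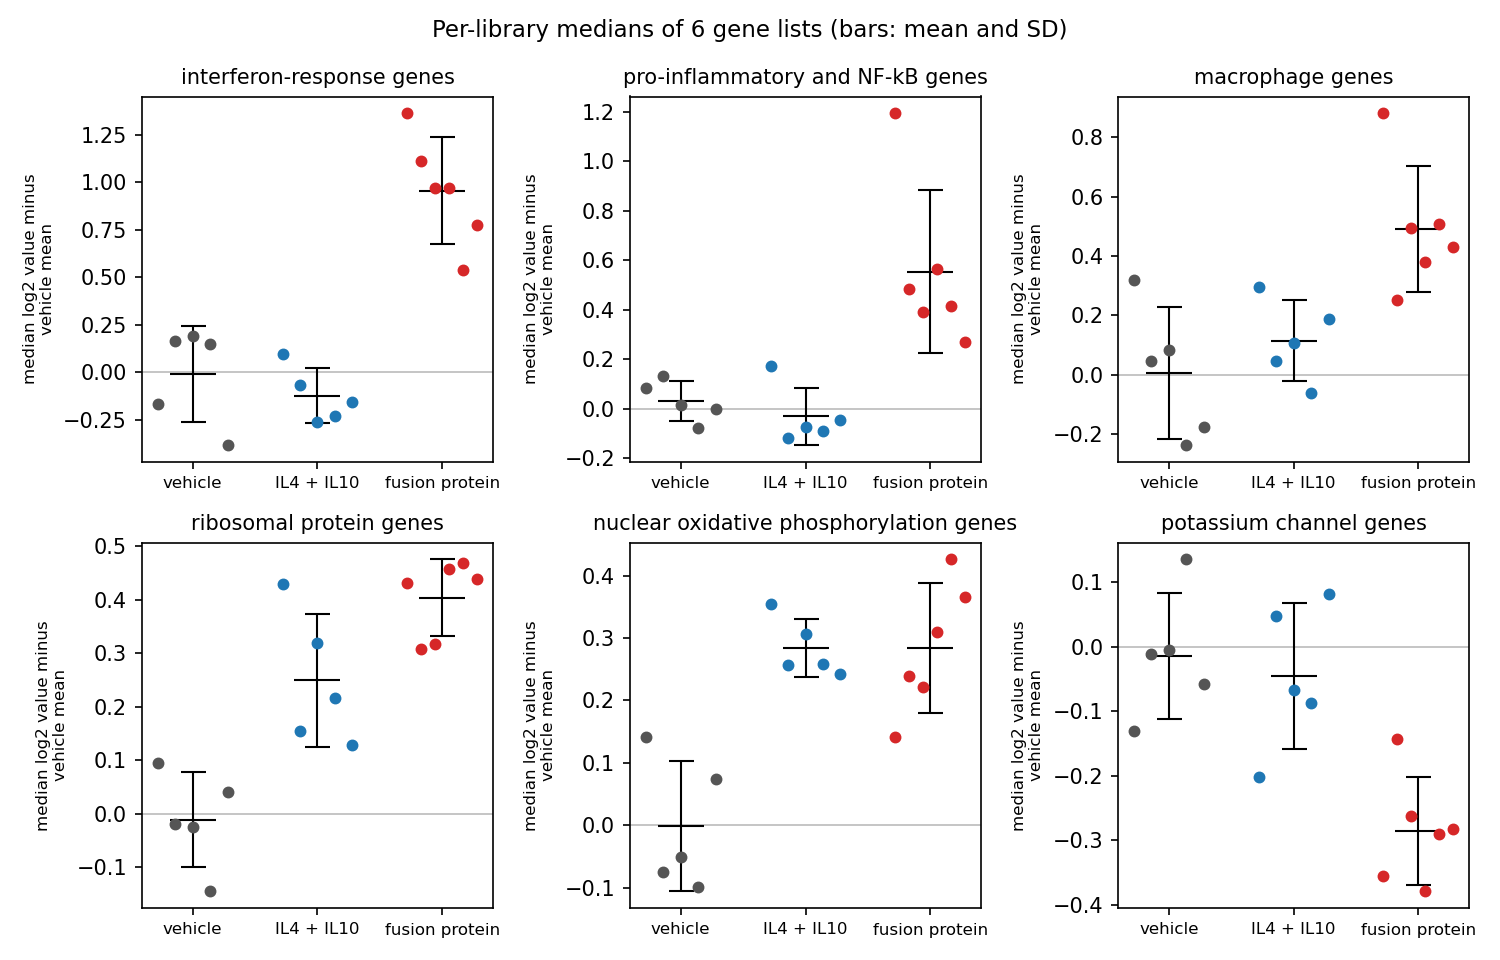
Median log2 value of the tested members of 6 gene lists in each library, minus the vehicle mean of each member, by treatment group; points are libraries and bars are the mean and SD. The 6 fusion protein libraries lie between 0.54 and 1.36 for interferon-response genes, above all vehicle and combination libraries, and the potassium channel medians of the fusion protein libraries, at -0.14 or below, lie under those of all vehicle libraries.

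The second comparison asks what the unlinked cytokines changed against vehicle. Nuclear genes of oxidative phosphorylation rose in 40 of 73 cases with 0 lower and 33 not passed, and 41 when adjusted over the list alone. The median was 0.28, with a camera adjusted p = 1.49e-06, and adjusted p = 0.744 with an estimated correlation. Uqcrb (ENSMUSG00000021520, chromosome 13, 66900617 to 66905378) rose by 0.84 ± 0.08 (adjusted p = 1.69e-06), from a scaled value of 1002 ± 103 (SD, n = 5) to 1886 ± 117 (n = 5), and Ndufa5, a subunit of complex I, by 0.65 ± 0.06. Ribosomal protein genes rose in 33 of 73 cases with 0 lower and 40 not passed, and 37 when adjusted over the list alone. The median was 0.23, with a camera adjusted p = 4.65e-06, and adjusted p = 0.744 with an estimated correlation. Among them Rpl36a rose by 0.84 ± 0.10 and Rpl35a by 0.61 ± 0.06. The GC slope of the combination libraries differed from that of vehicle. With GC and length trends removed, the oxidative phosphorylation median was 0.14 with 23 members called, Uqcrb differed by 0.47 and Ndufa5 by 0.29. With the late label number as a covariate the call of the oxidative phosphorylation list ended (median 0.20, adjusted p = 0.0689; 0.04 and 0.785 with trend removal in addition), and with quantile normalization its median was 0.16 and the ribosomal median 0.15.

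Immediate-early genes, which respond to activity and stress within minutes, fell in 7 of 19 cases with 0 higher and 12 not passed, and 7 when adjusted over the list alone. The median was -0.41, with a camera adjusted p = 3.19e-05, and adjusted p = 0.744 with an estimated correlation. Ier2, a regulator in this class, differed by -0.52 ± 0.11 and Junb, a component of AP-1, by -1.07 ± 0.32. With GC and length trends removed 2 members were lower and the median was -0.23, and with the late label number 3 were lower. With both together 0 were called and the median was -0.04 (adjusted p = 0.842), and Ier2 differed by -0.07 (0.758). The list had 4 members called under the stricter filter. Junb did not pass with the late label number (-1.16, adjusted p = 0.0619), nor in a fit of both groups alone (-1.07, 0.0649). Of 26 IL-10/STAT3 targets, 5 fell, 1 rose and 20 did not pass, and 4 and 1 when adjusted over the list alone. The median was -0.20, with a camera adjusted p = 0.0206, and adjusted p = 0.957 with an estimated correlation. That call ended without vehicle replicate 1 (median -0.09, adjusted p = 0.11), with GC and length trends removed (-0.15, 0.211), under the stricter filter (-0.16, 0.127) and with the late label number (-0.00, 0.406). With trend removal and the late label number together the median was 0.03 (0.992). The members called were 3 without vehicle replicate 2 and 3 without combination replicate 5, and the median was -0.31 without vehicle replicate 4. Receptor chains and signalling parts gave 1 higher, 3 lower and 9 not passed of 13, and 2 and 3 when adjusted over the list alone, and did not pass as a list (median 0.09, camera adjusted p = 0.416, and 0.957 with an estimated correlation), where median and mean (-0.092) differed in sign. The feedback inhibitor Cish passed (-0.33 ± 0.10, adjusted p = 0.0137), and it did not with GC and length trends removed (-0.10, 0.511) or with the late label number (-0.26, 0.129). Il4ra (-0.21 ± 0.17), Il10ra (0.09 ± 0.11), Il10rb (0.17 ± 0.07), Stat3 (-0.07 ± 0.10), Stat6 (0.11 ± 0.07) and Socs3 (-1.09 ± 0.48) did not pass.

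Interferon-response genes gave 0 of 30 members past the threshold with limma, 1 at an unadjusted p under 0.05, and a median of -0.14 (camera adjusted p = 0.126). The list passed as lower without vehicle replicate 5 (-0.22, adjusted p = 0.00642, 3 members called), without combination replicate 1 (-0.17, 0.0242), and with GC and length trends removed (-0.21, 0.0437). With the late label number its median turned to 0.22 (0.53), and with trend removal in addition to 0.05 (0.765). It was -0.21 without vehicle replicate 1 and -0.09 without vehicle replicate 4. Pro-inflammatory and NF-kB genes gave 0 of 17 past the threshold and 0 at an unadjusted p under 0.05, with a median of -0.02. Among single genes Rida, an enzyme that clears reactive imines, rose by 0.86 ± 0.10. Plec, a cytoskeletal linker, differed by -1.16 ± 0.09 and Hspg2, the basement membrane proteoglycan perlecan, by -1.09 ± 0.12; with GC and length trends removed these were -0.70 and -0.71. Lars2 fell by 2.80, and with the late label number the difference was -1.60 (adjusted p = 0.0915).

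In this comparison 3240 genes rose and 1651 fell, with 1 gene higher and 12 lower by 1 or more. The median GC content was 42.8% for the genes that rose and 51.9% for those that fell, and the differences correlated with GC content at r = -0.51 across genes. With GC and length trends removed 2057 genes rose, and with the late label number in addition 917 rose and 765 fell. Of the 4 lists past the threshold 0 passed with an estimated correlation, and 0 of 42 had an unadjusted p under 0.05. With fry, which does not compare a list with other genes, 2 of the 4 passed and 3 other lists did. Immediate-early genes (0.0562) and IL-10/STAT3 targets (0.498) did not. Satellite glia genes, not past with camera, had 8 of 16 members higher and 1 lower at an unadjusted limma p under 0.05. Their median lay above every vehicle library in all 5 combination libraries. Such counts were 12 and 4 of 22 for cholesterol synthesis and 8 and 2 of 14 for heat-shock genes, and 6145 of all 13385 genes had such a p. In 99 of 100 splits of the same libraries, the real one included, at least as many lists passed. A comparison within label numbers could not be made, since only 1 vehicle library has a late number and no combination library an early one.

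The third comparison sets the fusion protein directly against the combination, the question in the title of the series. Interferon-response genes were higher with the fusion protein in 29 of 30 cases, with 0 lower and 1 not passed, and 29 when adjusted over the list alone. The median was 1.16, with a camera adjusted p = 1.83e-36, and adjusted p = 0.0766 with an estimated correlation. Isg15 was higher by 2.09 ± 0.10 (adjusted p = 1.54e-10), at 633 ± 97.4 (SD, n = 6) against 73.2 ± 19.4 (n = 5) in scaled values, Irf7 by 1.89 ± 0.12 and Bst2, a tether of enveloped viruses, by 1.20 ± 0.12, and for Isg15 and Irf7 all 6 fusion protein libraries lay above every combination library. Among samples numbered 12 to 19 (2 against 5) the list median was 0.86 with 23 members called.

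Of 26 IL-10/STAT3 targets, 20 were higher with the fusion protein, 1 was lower and 5 did not pass, and 21 and 1 when adjusted over the list alone. The median was 0.90, with a camera adjusted p = 4.5e-16, and adjusted p = 0.156 with an estimated correlation. Slfn4 was higher by 3.24 ± 0.35, Saa3 by 2.64 ± 0.39 and Il1rn by 1.92 ± 0.32. Of this list 10 members were called with the late label number, under the stricter filter 13, and with the late label number and trend removal together 5 with a median of 0.60. Pro-inflammatory and NF-kB genes were higher in 13 of 17 cases, with 0 lower and 4 not passed, and 14 when adjusted over the list alone. The median was 0.66, with a camera adjusted p = 1.56e-13, and adjusted p = 0.156 with an estimated correlation. Ccl5 was higher by 2.03 ± 0.16 and Cxcl10 by 1.53 ± 0.21. Without combination replicate 4 the list had 8 members called. It had 6 with a median of 0.41 with the late label number, and under the stricter filter 4 with a median of 0.40. Macrophage markers gave 9 higher, 1 lower and 11 not passed of 21, and 11 and 1 when adjusted over the list alone. The median was 0.35, with a camera adjusted p = 1.54e-07, and adjusted p = 0.242 with an estimated correlation. Ctss was higher by 1.13 ± 0.17. With trend removal and the late label number together 1 member was called. Neutrophil and bone marrow markers gave 3 higher, 0 lower and 10 not passed of 13, and 3 when adjusted over the list alone. The median was 0.14, with a camera adjusted p = 0.00564, and adjusted p = 0.568 with an estimated correlation. The median rested largely on 1 library: fusion protein replicate 1 stood 1.257 above the vehicle mean and the other 5 at 0.138 ± 0.309 (SD), against 0.058 in the combination, and without this library the median was 0.01 (camera adjusted p = 0.0285). Csf3r and Cxcr2, receptors of granulocytes, and Lcn2 stood at 1.49 ± 0.34, 1.25 ± 0.34 and 1.04 ± 0.28. None of these 3 passed with the late label number (1.10, 0.83 and 0.85, adjusted p = 0.0512, 0.119 and 0.0786). Complement genes gave 5 higher, 2 lower and 7 not passed of 14, and 6 and 2 when adjusted over the list alone. Camera gave adjusted p = 0.000104, and adjusted p = 0.156 with an estimated correlation. C3 was higher by 1.21 ± 0.18.

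Receptor chains and signalling parts of IL4 and IL10 gave 6 higher, 1 lower and 6 not passed of 13, and 6 and 1 when adjusted over the list alone. The median was 0.09, with a camera adjusted p = 0.00129, and adjusted p = 0.156 with an estimated correlation. Il4ra was higher by 0.80 ± 0.16 (adjusted p = 0.00514), Il2rg by 0.42 ± 0.11 and Il10ra by 0.41 ± 0.10. With trend removal and the late label number together, Il4ra (0.55, adjusted p = 0.113) and Il10ra (0.30, 0.14) did not pass. Socs3 was higher by 1.52 ± 0.46 (adjusted p = 0.0256), a call that ended with GC and length trends removed (1.32, adjusted p = 0.0729), with the late label number (1.17, 0.129), and without combination replicate 2 (1.56, 0.0535), 4 (1.502, 0.0504) or 5 (1.49, 0.0536). Il10rb (-0.01 ± 0.06), Stat3 (0.06 ± 0.09), Stat6 (0.01 ± 0.06) and Cish (0.25 ± 0.10) did not pass. Of 18 IL-4/STAT6 targets, 6 were higher, 1 was lower and 11 did not pass, and 7 and 1 when adjusted over the list alone. The median was 0.30, with a camera adjusted p = 0.00564, and adjusted p = 0.568 with an estimated correlation. Arg1 stood at 1.49 ± 0.25 and Mgl2 at -0.88 ± 0.13. Per library the median of this list lay above every combination library in 4 of the 6 fusion protein libraries and below every one in 2. The call of this list ended with the late label number (median 0.26, adjusted p = 0.192), with trend removal in addition (0.10, 0.263) and under the stricter filter (0.03, 0.122). JAK-STAT feedback genes gave 4 higher, 1 lower and 8 not passed of 13, and 5 and 2 when adjusted over the list alone. Camera gave adjusted p = 0.0379, and adjusted p = 0.568 with an estimated correlation. The median of 0.23 was 0.15 without fusion protein replicate 1, and the call ended (adjusted p = 0.124). The median of that library was 0.362, against -0.102 in the other 5 and -0.092 in the combination.

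Immediate-early genes were higher in 7 of 19 cases, with 0 lower and 12 not passed, and 7 when adjusted over the list alone. The median was 0.39, with a camera adjusted p = 3.54e-08, and adjusted p = 0.242 with an estimated correlation. Junb was higher by 1.13 ± 0.30. With GC and length trends removed 2 members were called and the median was 0.20, with the late label number 2, and with both together 0, where the median was 0.06 (adjusted p = 0.426) and Junb did not pass (0.93, 0.1). The list had 4 members called without combination replicate 5 or under the stricter filter and 11 without combination replicate 1. Sensitiser receptors are a list of prostaglandin, bradykinin, protease and growth factor receptors that also holds cytokine and chemokine receptors. They gave 5 higher, 0 lower and 13 not passed of 18, and 5 when adjusted over the list alone. The median was 0.11, with a camera adjusted p = 8.64e-05, and adjusted p = 0.126 with an estimated correlation. Ccr2, the receptor that recruits monocytes, was higher by 1.20 ± 0.23. The 4 members with the lowest p were Ccr2, Tnfrsf1b, Tnfrsf1a and Il6ra, receptors of chemokines and cytokines and not of prostaglandins, bradykinin, proteases or growth factors. Endothelial markers gave 3 higher, 1 lower and 13 not passed of 17, and 3 and 1 when adjusted over the list alone. Camera gave adjusted p = 0.00901, and adjusted p = 0.156 with an estimated correlation. Lymphocyte markers gave 2 higher, 0 lower and 6 not passed of 8, and 2 when adjusted over the list alone. For these markers camera gave adjusted p = 0.0379, and adjusted p = 0.568 with an estimated correlation, and without fusion protein replicate 1 the median fell from 0.08 to 0.03 and the call ended (0.134). Gzma, a protease of cytotoxic cells, was higher by 0.69 ± 0.11. MHC class II genes gave 1 higher, 0 lower and 6 not passed of 7, and 1 when adjusted over the list alone. The median was 0.14, with a camera adjusted p = 0.0118, and adjusted p = 0.568 with an estimated correlation. The member called was Ciita, their transactivator, at 0.34 ± 0.09, and it did not pass with the late label number (0.23, adjusted p = 0.097).

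Nerve injury and regeneration genes gave 5 higher, 1 lower and 10 not passed of 16, and 5 and 1 when adjusted over the list alone. Camera gave adjusted p = 0.00564, and adjusted p = 0.263 with an estimated correlation. Tubb6, a tubulin, was higher by 0.92 ± 0.18. Unfolded protein response genes gave 3 higher, 1 lower and 13 not passed of 17, and 1 and 0 when adjusted over the list alone. Camera gave adjusted p = 0.00403, and adjusted p = 0.464 with an estimated correlation, and without fusion protein replicate 1 the calls were 1 higher and 1 lower (0.0263). Ribosomal protein genes gave 15 higher, 1 lower and 57 not passed of 73, and 7 and 0 when adjusted over the list alone. The median was 0.11, with a camera adjusted p = 2.36e-07, and adjusted p = 0.333 with an estimated correlation. Rpl18 was higher by 0.51 ± 0.12. The calls of this list numbered 4 without combination replicate 5, 6 without fusion protein replicate 4, 7 without fusion protein replicate 5 or combination replicate 2, 10 without combination replicate 4 and 30 without combination replicate 1. With quantile normalization the ribosomal median was 0.24. With GC and length trends removed it was 0.07 with 7 called, and with the late label number in addition 0.05 (adjusted p = 0.102). With the late label number alone 30 were called. Nuclear genes of oxidative phosphorylation did not pass as a list (4 higher, 10 lower, 59 not passed, camera adjusted p = 0.128), and their median of -0.02 and mean of 0.05 differed in sign. The list passed as higher with quantile normalization (median 0.11, adjusted p = 0.000213), with the late label number (0.07, 0.00079) and without combination replicate 1 (0.01, 0.0248). It also passed without fusion protein replicate 1 (-0.01, 0.0361), without fusion protein replicate 2 (-0.01, 0.0403) and under the stricter filter (-0.02, 0.032), where the median stayed below 0.

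Potassium channel genes were lower with the fusion protein than with the combination in 15 of 32 cases, with 0 higher and 17 not passed, and 16 when adjusted over the list alone. The median was -0.22, with a camera adjusted p = 0.00759, and adjusted p = 0.568 with an estimated correlation. Kcnd3 differed by -0.36 ± 0.10 (-0.21 with quantile normalization). The list had 6 members called without combination replicate 2, 7 without combination replicate 5 or fusion protein replicate 4, 6 with quantile normalization and 5 with GC and length trends removed, where the medians were -0.13 and -0.14. Of 23 sodium and calcium channel genes 9 were lower, 0 higher and 14 did not pass, and 10 when adjusted over the list alone. The median was -0.22, with a camera adjusted p = 0.0304, and adjusted p = 0.594 with an estimated correlation. Scn3b, an auxiliary sodium channel subunit, differed by -0.32 ± 0.08 (-0.19 with quantile normalization). The call of the list ended without combination replicate 5 (median -0.18, adjusted p = 0.0815), with the late label number (-0.23, 0.0536) and under the stricter filter (-0.22, 0.0705), where the median stayed about as large, and with quantile normalization (-0.10, 0.132). Without combination replicate 1, 14 members were called, and with GC and length trends removed the median was -0.11. Other lists of neuronal genes had lower members as well and did not pass: pan-neuronal genes (0 higher, 8 lower and 11 not passed of 19, median -0.17, camera adjusted p = 0.455, and 0.826 with an estimated correlation), nociceptor genes (0, 7 and 20 of 27, -0.14, 0.455 and 0.818), myelinated afferent genes (0, 5 and 12 of 17, -0.08, 0.532 and 0.826) and inhibitory receptors (0, 4 and 18 of 22, -0.17, 0.069 and 0.594). The lower counts were the same 8, 7, 5 and 4 when adjusted over the list alone. Lower members were not particular to neuronal lists. Satellite glia genes gave 1 higher and 9 lower of 16 (median -0.24, camera adjusted p = 0.138), and myelinating Schwann cell genes 1 and 5 of 20 (-0.20, 0.559). Cholesterol synthesis genes gave 1 and 10 of 22 (-0.15, 0.241). Over all 13385 tested genes 2966 were lower, with a median difference of -0.09.

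In all, 984 genes were higher and 2966 lower with the fusion protein than with the combination, 100 of them by 1 or more upward and 1 downward. The counts were 1143 and 2301 with median centring, 972 and 1411 with quantile normalization, 1342 and 3046 with the late label number, 656 and 913 with GC and length trends removed, and 448 and 444 with trend removal and the late label number together. Similar totals can hold different genes: with the late label number 666 of the 984 higher and 2150 of the 2966 lower genes stayed called. The counts fell to 547 higher and 1452 lower without combination replicate 2, to 646 and 1850 without combination replicate 5, and to 1869 lower without fusion protein replicate 4. Among samples numbered 12 to 19 alone (2 against 5), 1389 genes were higher and 2462 lower. Of these, 669 and 1670 were also called in the same direction with all libraries. Of the 19 lists past the threshold, 0 passed with an estimated correlation, and 8 of 42 had an unadjusted p under 0.05. Of the 19, 11 passed with fry, and 3 other lists did. The 8 that did not were those of ribosomal proteins (0.119), IL-4/STAT6 targets (0.298), neutrophils (0.381), the unfolded protein response (0.138), nerve injury (0.0798), MHC class II, lymphocytes and JAK-STAT feedback. In 34 of 100 splits of the same libraries, the real one included, at least as many lists passed.

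Many genes differed from vehicle in the same direction with both treatments. Of the genes past the threshold against vehicle, 1086 rose in both treatments, 894 fell in both and 7 went opposite ways. The vehicle libraries are shared, so that independent lists are no reference for these counts: across all genes the sign was the same in 67.61%, and in 67.53% in simulations without effect. In 20 further simulations without effect, on average 0 genes were called higher in both and 0 lower in both. Their errors were independent between genes, unlike those of real libraries. With the vehicle libraries split between the comparisons, 449.7 genes rose in both on average over 20 splits, where independent lists would share 135.7, and 399.3 fell in both, against 85.94. Of the 1086 genes that rose in both, 15 were higher and 231 lower with the fusion protein in the direct test and 840 did not differ detectably; of the 894 that fell in both the counts were 82, 14 and 798. Of the 518 genes that rose with the fusion protein and did not pass with the combination, 305 were higher in the direct test, and of the 2153 that rose with the combination and did not pass with the fusion protein, 1306 were lower in it. The log2 differences from vehicle correlated at r = 0.51 (Spearman rho = 0.58) across genes, where the 100 simulations without effect gave 0.52. Their covariance was 0.0332 against 0.00546 in them, and with the vehicle libraries split the correlation was 0.42 on average (0.12 to 0.68).

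**Figure D3:**
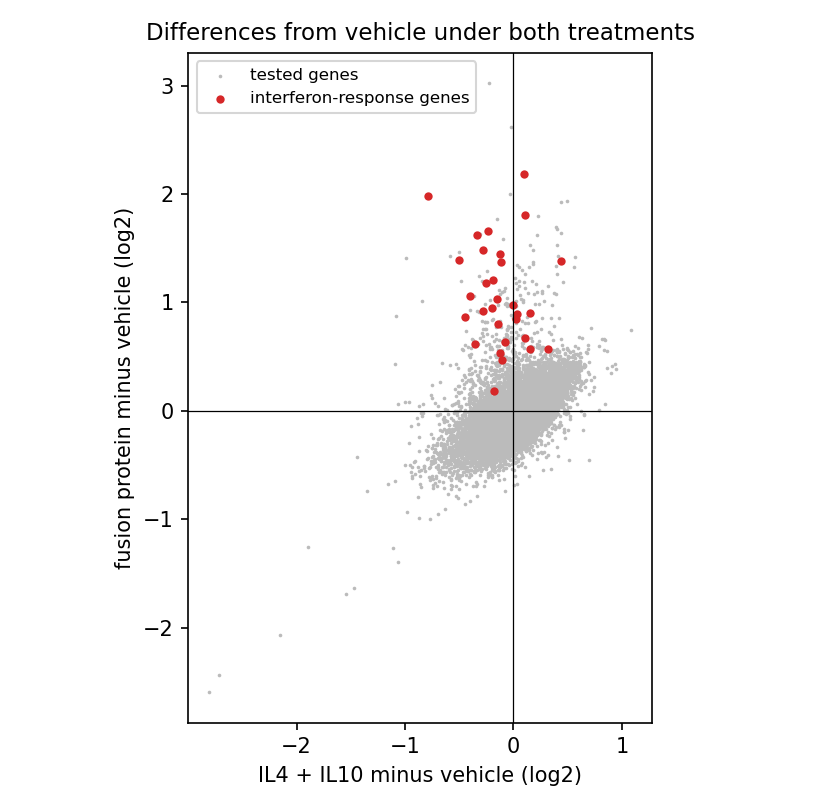
Log2 difference from vehicle with the combination (horizontal axis) and the fusion protein (vertical axis) for the 13385 tested genes in grey, with the 30 interferon-response genes in red. The 30 red points lie above 0 for the fusion protein, with a median of 0.96, and around -0.14 for the combination.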

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

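All tests of explanations and of other splits in this part were chosen after the results were seen, while the measure of distance from the other libraries of a group was fixed before the data were examined. That measure is the gap between the highest or lowest library and its nearest neighbour, divided by the range of the group. It exceeded the 95% critical value in 45 of 558 groups of values (41 of 477 for genes, 4 of 66 for list medians and 0 of 15 for library measures), and chance gives about 1 in 20.

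Fusion protein replicate 1 accounts for 19 of the 45, 17 of them genes. It was far above the other fusion protein libraries for Slfn4 (0.633), Saa3 (0.789), Arg1 (0.626), Il1b (0.63), Fcgr1 (0.749), Tlr2 (0.782), Ctss (0.635), Fcer1g (0.631), Il4ra (0.798) and Il13ra1 (0.699). The same holds for Pim1 (0.809), Tnfrsf1b (0.706), Csf3r (0.627), Cxcr2 (0.777) and Creld2 (0.835), and for the medians of the IL-10/STAT3 targets (0.696) and the pro-inflammatory and NF-kB genes (0.681). It was far below the others for Arc (0.637) and Gjc3 (0.82). Combination replicate 1 accounts for 7, being high for Cxcl9 (0.839), Serping1 (0.737), Ighm (0.727) and the pro-inflammatory list (0.747) and low for Hspa5 (0.749), Hsp90b1 (0.835) and the heat-shock list (0.829).

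The other libraries account for 1 to 4 each or for none. Vehicle replicate 1 was low for Nav2 (0.769) and Scn1a (0.749) and high for Il2rg (0.883) and Zfp979 (0.741). Vehicle replicate 3 was low for Eng (0.913), vehicle replicate 4 high for Atp5h (0.719) and Sox17 (0.746), and vehicle replicate 5 low for Irf7 (0.796). Fusion protein replicate 2 was low for Bst2 (0.644) and Lck (0.67), replicate 3 low for Atp5h (0.793), replicate 4 high for Nav2 (0.749) and low for Stat6 (0.648), and replicate 6 high for Ifit3b (0.642) and Rps16-ps2 (0.646). Combination replicate 2 was low for Gal (0.801), and combination replicate 5 high for Pdia4 (0.831) and Cd163 (0.77) and low for Sbno2 (0.837).

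The first pattern is the distance of fusion protein replicate 1. More blood in the sample is argued against by the erythrocyte list, whose median in this library was 0.202 above the mean of the other 5 (SD 0.344), while the neutrophil list stood at 1.26 against 0.138 ± 0.309. In scaled values Hbb-bs was 1669 (675 to 3558 in the others), Cxcr2 1152 (154 to 261) and Csf3r 1934 (274 to 605). A library of another group under this label is argued against by the interferon list, whose median lay 1.174 above the highest vehicle or combination library. No biological explanation was tested, and a stronger local inflammation in this sample stays open.

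The second pattern is the higher level of interferon-response genes with the fusion protein than with the combination. A larger share of macrophages that raises both lists alike is argued against as the whole cause. The interferon median minus the macrophage median differed by 0.702 between the groups (exact permutation p = 0.00433, two-sided). The lowest fusion protein library stood at 0.033 and the highest combination library at -0.112. Macrophages with more interferon-response RNA per cell would widen this difference as well, so it cannot decide on a change in their kind. A difference between the early and the late label numbers as the whole cause is argued against by the median of 0.863 among samples numbered 12 or above. That test cannot decide on a finer effect of label order. The combination libraries are numbered 13 to 17 and the 2 late fusion protein libraries 12 and 19. Another active substance in the fusion protein preparation cannot be told apart from the treatment, since every fusion protein library received it; the pro-inflammatory and NF-kB median was 0.657 higher. An effect of the fusion protein itself stays open beside it.

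The third pattern is the set of genes that differed from vehicle in the same direction with both treatments. Chance values of the shared vehicle libraries are argued against by the covariance of both differences, which was at least 0.01056 in 20 splits of the vehicle libraries. Trends of GC content and gene length as the whole cause are argued against by a test with these trends removed and the vehicle libraries split between the comparisons: 378.6 genes were higher in both on average over the 20 splits, where independent lists would share 71.33, and 253.5 were lower, where they would share 45.96. RNA or library quality of the vehicle samples cannot be told apart from the treatments: the mean length slope of vehicle libraries was 0.104 above that of treated libraries, and all 5 vehicle libraries lay above all treated ones. An effect common to both treatments stays open.

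The number of genes past the threshold argues against a random grouping of the libraries in each comparison. In each, 1 of 100 splits, the real one, gave as many, and 1 in 100 is the smallest share this test can give. The counts were 3450 genes against 2339 in the highest other split for the fusion protein against vehicle. They were 4891 against 0 for the combination against vehicle, and 3950 against 1168 for the direct comparison. Splits cannot exclude a cause that follows the groups, such as the label numbers or the length slope. For the number of gene lists chance could not be excluded: 64, 99 and 34 of 100 splits gave at least as many. The real split gave 13, 4 and 19 lists, and the highest other split 29, 22 and 32. These splits count lists and test no single list. For the interferon list, picked for its large difference, the lowest fusion protein library stood at 0.541 and the highest combination library at 0.098. An exact permutation test of these library medians gave p = 0.00216 (two-sided).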

How the results depend on the processing

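The removal of GC and length trends, alone or with the late label number, and the omission of fusion protein replicate 1 with vehicle replicate 1 were chosen after seeing the data. Of 209 gene results 186 passed the threshold. Single omissions ended a call in 98 cases over 19 genes, other alternatives in 152, and the omission of fusion protein replicate 1 with vehicle replicate 1 in 6. Where not stated otherwise, the cause was not tested. With fewer genes in the stricter filter the correlation of both treatments was 0.549, on log2 of the decoded value plus 1 it was 0.472, with GC and length removed 0.465, with the vehicle libraries split 0.418 and without fusion protein replicate 1 and vehicle replicate 1 0.536. Counts are given as higher and lower. Array weights gave 2755 and 3351 for the fusion protein against vehicle and 1590 and 4685 for the direct comparison. The first residual principal component gave 1708 and 4511 for the direct comparison, and quantile normalization 1411 lower. An adjusted p under 0.01, a stricter threshold by construction, gave 836 and 932, 2014 and 977, and 297 and 611 in the order of the report. With GC and length removed 2057 genes were higher with the combination than in vehicle and 913 lower in the direct comparison. With the late label number in addition the counts were 917 and 765, and 448 and 444, with 1 and 11 lists. With the late label number alone 2 lists passed for the combination. With an estimated correlation 0, 0 and 0 lists passed.

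Reversed were Asns in the direct comparison with quantile normalization (0.005 from -0.169) and, with GC and length removed and the late label number, Cish (0.023 from -0.331), Cebpb (0.192 from -0.383) and the IL-10/STAT3 list (0.033 from -0.196) for the combination, and Ier2 (-0.012 from 0.413) and Creld2 (-0.033 from 0.298) in the direct comparison. The oxidative phosphorylation median of the direct comparison (-0.015) was 0.106 with quantile normalization, 0.073 with the late label number, 0.079 with GC and length removed in addition, and -0.026 to 0.009 with a library omitted. Omitting each library gave 1165 to 1758 higher and 1331 to 2086 lower for the fusion protein, and 2644 to 3751 and 1389 to 1803 for the combination. The direct comparison gave 547 (without combination replicate 2) to 1201 higher and 1452 to 4046 lower (without combination replicates 2 and 1), and 1341 higher without fusion protein replicate 1 and vehicle replicate 1. The correlation ranged from 0.444 to 0.541 and the lists from 12 to 15, 4 to 6 and 17 to 21. Samples of different groups share replicate numbers. The 15 pairs of equal number had a mean residual correlation of 0.141 (-0.196 to 0.598), against -0.031 (-0.858 to 0.796) for 70 others. Of the 16 libraries, 6 were closest to their own number, and no chance value was computed for this count. These values do not settle whether the groups were paired, and the main model did not treat them as paired. With the replicate block the counts were 1538 and 1678, 3474 and 1721, and 889 and 2540. Without fusion protein replicate 1 the adipocyte (median 0.25) and mitochondrially encoded lists (-0.39) passed in addition in the direct comparison (adjusted p = 0.0285 for both).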

Other observations

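The gene families of this part and all their tests were chosen after the results were seen. With the fusion protein against the combination, genes of antigen processing were higher: of Psmb8, Psmb9, Psmb10, Tap1, Tap2 and Tapbp, subunits of the immunoproteasome and parts of peptide transport, 6 of 6 passed (median 0.89). MHC class I chains were higher in 8 of 10 cases (median 0.50), guanylate-binding proteins in 6 of 6 (1.27) and schlafens in 6 of 6 (1.09). Interferon-induced transmembrane proteins were higher in 4 of 5 cases (0.95) and serum amyloid A genes in 3 of 3 (2.01). The direction of these medians held with quantile normalization, median centring and the removal of GC and length trends. These families were picked for their high values, so no p-value is given for them. The wider family of 21 proteasome subunits gave 6 higher and 6 lower, with a median of -0.08 that was 0.08 with quantile normalization. For the combination against vehicle limma gave 0 calls among the guanylate-binding proteins, schlafens, interferon-induced transmembrane proteins and serum amyloid A genes, with 0 at an unadjusted p under 0.05, and 0 among MHC class I chains, with 3 at an unadjusted p under 0.05.

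Against vehicle 7 genes passed in opposite directions with both treatments. Tapbp differed by 0.27 with the fusion protein and -0.39 with the combination, Tap2 by 0.57 and -0.47, Siglec1, a sialic acid receptor of macrophages, by 0.30 and -0.32, and Mvp, the major vault protein, by 0.51 and -0.41. Fes, a tyrosine kinase of myeloid cells, differed by 0.34 and -0.39, Parp10 by 0.46 and -0.36 and Mgl2 by -0.53 and 0.35. The call of Mgl2 for the combination ended with the late label number (0.085, adjusted p = 0.697), and the other 6 genes were not tested under alternatives. The metallothioneins Mt1 and Mt2, which bind metals, were higher with the fusion protein than with the combination by 1.86 ± 0.43 and 2.40 ± 0.51, and neither passed against vehicle. Transcripts of Il4, Il10 and Ifng stayed at scaled values of 6 or below, and Ifnb1 lay at the floor in every library.

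The deposited p-values, whose comparison is not named, ranked the genes much as a test of all treated libraries against vehicle does (Spearman rho = 0.975 across genes, which are not independent replicates). The rho was 0.654 for the fusion protein against vehicle, 0.703 for the combination against vehicle and -0.0194 for the direct comparison. Of 3567 tested genes with a deposited adjusted p under 0.05, 2965 were also called for treated against vehicle.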
